A study of Mus musculus with 5 samples.

How the data were processed

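Droplet single-cell RNA sequencing was done on dissociated mouse lung tissue, with 10x Genomics 3′ libraries. There were 5 libraries, all labelled male, C57B6J and 39 weeks of age. Tumours picked under a dissecting microscope came from KrasLA1 mice (2 libraries) and from KrasLA1;Dicer1S2D mice (2 libraries). KrasLA1 is a latent allele that yields oncogenic Kras, and Dicer1S2D is a phosphomimetic allele of Dicer1. The fifth library came from a Dicer1S2D mouse; its title says lung tissue, whereas its tissue label says lung tumours. The labels do not say how many animals or tumours entered each library, so p-values measure the spread between these libraries. The names of the deposited files carry the same tag for both double-mutant libraries and a different tag for each KrasLA1 library. What the tag stands for is not stated, and the 2 double-mutant libraries may share an animal or a tumour.

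The deposited matrices hold raw UMI counts per gene and barcode, with no normalization. Per the file headers, the authors made them with Cell Ranger 3.1.0, and the labels name the genome build mm10. FastQC and Seurat are named there without a version or a stated role. The deposited barcode and feature lists hold names only. Each matrix had 31053 features, and the lowest total of any barcode was 500 UMIs. Gene positions came from GENCODE vM21 on GRCm38, which matched 30934 features by Ensembl ID, 30445 of them with the same symbol.

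Barcodes with at least 300 genes, at least 500 UMIs and at most 20% mitochondrial UMIs were kept. The barcodes with the highest scrublet scores were removed from each library as doublets, at 0.8% per 1000 deposited barcodes. Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes, 30 principal components and 15 neighbours then gave 34 Leiden clusters at resolution 1.0, without integration across libraries (scanpy 1.11.5, igraph 0.11.9, Python 3.11.15). Of all barcodes, 28067 were kept.

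Clusters were named by fixed markers, and each name carries "-like". A name needed at least 3 markers found in at least 10% of the cluster's cells and above the other cells, and at least as many markers among its 10 leading genes as any other class. Leading genes ranked by fold over all other cells, with 20 CPM added, among genes found in at least 25% of the cells. Club and ciliated cells fell into 1 cluster and were treated as airway epithelial-like. Tumour epithelial cells are the epithelial clusters other than AT1-like, airway and mesothelial ones: 3 AT2-like clusters and 1 unnamed epithelial cluster. Dissection and clustering do not separate tumour cells from normal alveolar type 2 cells. The unnamed cluster is led by Gkn2, Clu, Meg3 and Krt18, which differ between libraries, so its share is not read as a difference between genotypes, although it was among the classes tested.

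The 2 KrasLA1 and the 2 double-mutant libraries were compared on raw UMIs summed per library and cell class. The test was the edgeR 4.0.16 quasi-likelihood test with TMM scaling and filterByExpr in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors of log2 folds are the fold divided by the square root of F. A class was tested when each tumour library held at least 20 of its cells. The same test was run on cell numbers per class, with all kept cells as library size. CPM means UMIs per 1000000 UMIs of that class and library, and errors are SD over libraries unless called SE.

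Of 33 gene lists, 23 were tested in tumour epithelial cells with camera (limma 3.58.1) at its preset inter-gene correlation of 0.01. A further 5 lists marked RNA of other cells or RNA quality and were adjusted on their own. Each set test was repeated with an estimated correlation and with fry. Members of each list were also adjusted over the list alone.

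Shares of cells were taken after thinning each cell at random to 2000 UMIs; cells below that were left out. A cell counted as gastric with at least 2 UMIs of the 16 gastric genes that remain without Pgc, Muc1, Aqp5 and Agr2, which lung cells also express. A cell counted as proliferating with at least 3 UMIs of 24 proliferation genes. Shares carry exact 95% Clopper-Pearson intervals (scipy 1.17.1), and a count of 0 allows up to 3 counts; intervals and floors cover counting error only. Library shares were compared with an exact permutation test of the difference of means in either direction, whose smallest p with 2 libraries against 2 is 0.333. The Dicer1S2D library has no replicate, so its AT2-like cells were set beside the tumour libraries by a size rule without a test. A gene counted when it lay at least 4-fold above or below all 4 tumour libraries and reached 50 CPM in the lung library or the nearest tumour library, whichever was higher. RNA of other lung cells in them was scaled to S100a8 or S100a9, whichever gave more, with the neutrophil-like class, each of its clusters or all non-epithelial cells as the source, a calculation added after the values were seen.

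Cell filters, tests, markers, gene lists, size rules, the alternatives and the rule for naming genes were fixed before the data were examined. The rule names up to 10 genes per direction past the threshold and otherwise genes in order of p, up to 5 per direction. It adds Kras, Dicer1, every gastric gene that passes the count filter and up to 4 members of each called list, and in other classes up to 3 genes per direction with at least 10 CPM in the higher group. A gene chosen after its values were seen is marked as such. The details of cluster naming beyond the markers were settled on the clusters, before any test between genotypes.

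The test was tried on simulated data with the spread of the 4 tumour epithelial libraries. Of the genes made 2-fold different, 14.2% were called, of 4-fold genes 84.8% and of 8-fold genes 98.3%, with 4.09% false calls. With the lower spread found without double-mutant library 2, these shares were 37.0%, 99.7% and 100%. At that lower spread, a list of 15 genes raised 2-fold was called in 10 of 10 simulations and a flat list in 0 of 10. A simulated list counted as called at an unadjusted camera p under 0.05, a looser rule than the adjusted p used for the real lists. Genes were drawn independently of each other. The simulation therefore does not tell how often camera calls a list of correlated genes that did not change. For cell numbers, a 4-fold change in a class was called in 4 of 10 simulations and a 16-fold change in 9 of 10.

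Alternatives covered lenient and strict cell filters, doublets left in, clustering at resolutions 0.5 and 2.0, other populations, DESeq2 1.42.0 size factors and tests, no filter on low counts, robust dispersion, replicate number as a block, equal cell numbers, other UMI minima and thinning depths, and leaving out each library in turn. The last leaves 1 library in a group, which edgeR then takes to vary like the libraries of the other group. Integration across libraries, copy-number calls and trajectories were not analysed here.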

Results

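The dataset held 5 droplet libraries of mouse lung: 2 of KrasLA1 tumours, 2 of KrasLA1;Dicer1S2D tumours, called double mutant below, and 1 of Dicer1S2D lung tissue without a replicate. The series states that the tumour libraries were made to compare tumour cell populations between the 2 tumour genotypes. KrasLA1 library 1 had 34321512 UMIs in 13222 barcodes, and library 2 had 28909666 UMIs in 6992 barcodes. Double-mutant library 1 had 30114289 UMIs in 7909 barcodes, and library 2 had 41410470 UMIs in 10845 barcodes. The Dicer1S2D lung library had 29712543 UMIs in 7288 barcodes. After filtering, these libraries kept 7756, 4747, 4788, 4174 and 6602 cells, in that order. Before filtering, the median share of mitochondrial UMIs was 23.4% in double-mutant library 2, between 11.2% and 12.7% in the other tumour libraries and 2.81% in the lung library.

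Tumour epithelial cells numbered 1313 and 1027 in the KrasLA1 libraries and 841 and 1154 in the double-mutant libraries, with 5688797 to 15752705 UMIs per library. Values of a gene in these cells are given for KrasLA1 libraries 1 and 2 and then double-mutant libraries 1 and 2. Kras, on chromosome 6 from 145216699 to 145250239, had 146, 151, 163 and 192 CPM. Dicer1, on chromosome 12 from 104687742 to 104751952, had 32.9, 30.0, 31.6 and 35.6 CPM. Their log2 folds, double mutant over KrasLA1, were 0.09 ± 0.23 and -0.06 ± 0.23 (SE, n = 2 against 2). Folds are relative to a TMM shift of 0.16 (log2) toward higher CPM in the double mutant, which turns the sign for Dicer1: its mean CPM was 31.5 in KrasLA1 and 33.6 in the double mutant. In the 72 such cells of the Dicer1S2D lung library, Kras had 96.8 CPM and Dicer1 31.9 CPM. Reads from the 3′ ends of transcripts do not tell the alleles apart.

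In tumour epithelial cells, the genes with the lowest p and higher counts in the double mutant were Vcam1, an adhesion molecule that binds leukocytes, Fgf2, a growth factor, and Spp1, the secreted matrix protein osteopontin. Vcam1, on chromosome 3 from 116109949 to 116129688, had a mean of 3.39 ± 1.65 CPM in KrasLA1 and 47.2 ± 23.2 CPM in the double mutant (SD, n = 2 each). Spp1, on chromosome 5 from 104435118 to 104441050, had 6.84 ± 2.07 and 100.3 ± 82.6 CPM, and Fgf2, on chromosome 3 from 37348346 to 37410108, had 1.85 ± 0.540 and 14.7 ± 6.13 CPM. Their log2 folds were 3.63 ± 0.50, 3.67 ± 0.64 and 2.81 ± 0.44 (SE). In such cells of the single Dicer1S2D lung library, Vcam1 had 134 CPM, above every tumour library, whereas Spp1 had 2.28 CPM and Fgf2 0 UMIs. Next in order were the glypican gene Gpc6, with 0.814, 1.18, 4.57 and 18.2 CPM, and Pbld2, with 4.40, 4.59, 11.3 and 22.7 CPM. On the lower side stood the chemokine gene Cxcl1, with 7.49, 3.41, 0.703 and 0.381 CPM, the interferon-induced antiviral gene Rsad2, with 9, 14, 0 and 2 UMIs, and Epdr1, with 21.8, 27.5, 12.3 and 9.97 CPM. The nuclear receptor gene Nr4a3 had 10.4, 7.73, 3.34 and 2.09 CPM, and the semaphorin gene Sema5a 4.88, 6.42, 2.11 and 1.14 CPM.

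None of these passed the test: of 11815 genes, the edgeR quasi-likelihood test called 0 after Benjamini-Hochberg adjustment, with 202 at an unadjusted p under 0.05. The latter are fewer than this threshold gives when no gene changes. DESeq2 called 3 genes, all higher, which were Vcam1, Spp1 and Fgf2 (adjusted p = 5.52e-08, 4.50e-07 and 0.00992, with both double-mutant libraries above both KrasLA1 libraries for each gene). With replicate number as a block, edgeR called 2 other genes, Fermt1 and Bpifa1, chosen here after their values were seen. Fermt1 had 0, 0, 13 and 571 UMIs, and the airway secretory gene Bpifa1 had 0, 29, 2 and 1812 UMIs. The fold of Spp1, which macrophages also express, was 1.30 on the log2 scale with doublets left in and 2.22 in AT2-like clusters alone. Vcam1 in these clusters had 1.94, 1.21, 4.20 and 29.9 CPM, so that double-mutant library 1, at 30.8 CPM with the unnamed cluster, was at 4.20 CPM without it; Fgf2 had 0.969, 1.03, 5.88 and 9.72 CPM.

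Double-mutant library 2 stood apart from the other 3 in these cells. Across genes, which are not independent replicates, the correlation of its log CPM with each of the others was 0.912 to 0.920, against 0.963 to 0.975 among the others. Its tumour epithelial cells had a median of 6712 UMIs, against 2044, 3058 and 2197. Other clusters held them: the unnamed cluster, led by Gkn2, Clu, Meg3 and Krt18, had 7.46%, 10.4%, 6.42% and 39.6% of the tumour epithelial cells, and the deepest AT2-like cluster 41.7%, 36.7%, 32.7% and 12.5%. Without double-mutant library 1, which leaves library 2 alone in its group, edgeR called 961 genes (549 higher and 412 lower). Without double-mutant library 2 it called 2 genes, Vcam1 and Spp1, both higher (adjusted p = 0.0131 for both). Without any filter on low counts it called 301 genes.

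**Figure D1:**
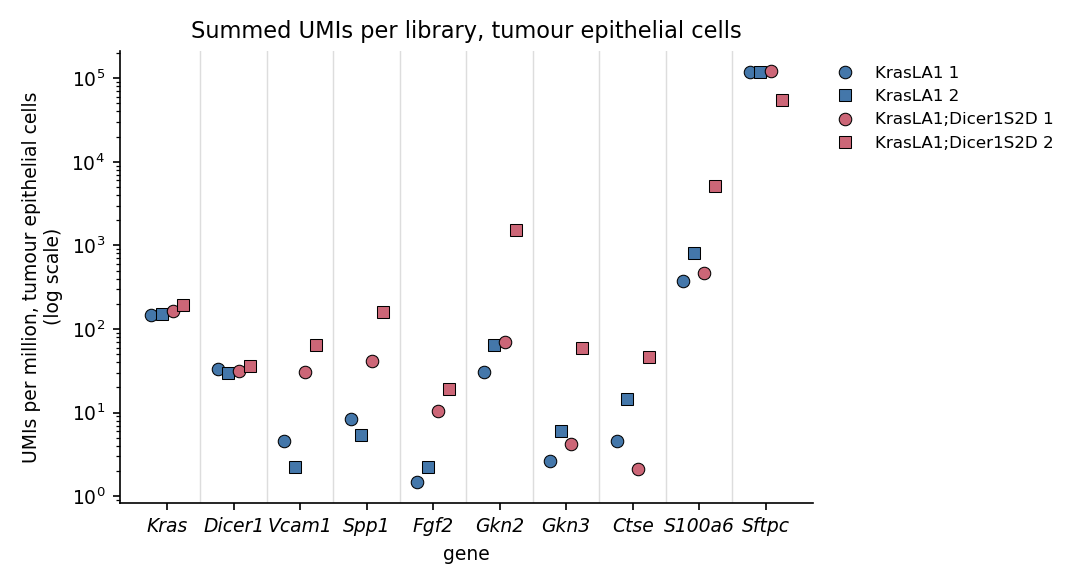
Counts in CPM of 10 genes in tumour epithelial cells (log scale), 1 point per library, with colour for genotype and symbol for replicate. Vcam1 is between 2.23 and 4.56 in KrasLA1 and between 30.8 and 63.5 in the double mutant, whereas Gkn2 is between 30.3 and 70.1 in 3 libraries and at 1522 in double-mutant library 2.

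The list of gastric secretory and surface genes was chosen because the title of the series names a gastric cell fate. Its 9 measured members, of 20, did not move as a group. The gastrokine genes stood out in double-mutant library 2, and Tff1 and Muc5ac had most of their UMIs in that library and KrasLA1 library 2. Gkn2, a gastrokine of the stomach's surface cells on chromosome 6 from 87373357 to 87379497, had 30.3, 63.8, 70.1 and 1522 CPM, a log2 fold of 3.85 ± 1.26 (SE, n = 2 against 2), or 0.52 without double-mutant library 2 and 4.77 without library 1 (adjusted p = 0.000239). Its neighbour Gkn3 had 2.60, 6.03, 4.22 and 59.2 CPM, and Ctse, encoding cathepsin E, had 4.56, 14.4, 2.11 and 46.0 CPM. The trefoil factor gene Tff1 had 0, 41, 0 and 77 UMIs, and the gastric mucin gene Muc5ac had 1, 19, 0 and 27 UMIs. Muc1 had 427, 492, 553 and 272 CPM, and Aqp5 had 570, 639, 503 and 409 CPM, both of which normal lung epithelium also expresses. Pgc, which encodes pepsinogen C, and Dpcr1 stayed under 3 CPM in all 4 libraries. Of 9 members measured, 5 were higher and 4 lower, 0 changed by edgeR and 0 adjusted over the list alone, with 2 at an unadjusted p under 0.05. The list was not called (camera, adjusted p = 0.282, and adjusted p = 0.801 with an estimated correlation). Without double-mutant library 1 it was higher (adjusted p = 1.35e-08), without KrasLA1 library 2 as well (adjusted p = 0.000135), and without double-mutant library 2 it was lower (adjusted p = 0.0304).

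Counted by cell at 2000 UMIs each, 1.5% and 2.53% of KrasLA1 tumour epithelial cells were gastric (exact 95% intervals 0.723% to 2.75% and 1.42% to 4.13%, of 665 and 594 cells). The double-mutant libraries had 1.82% and 40.7% (0.788% to 3.55% and 37.2% to 44.2%, of 440 and 784 cells). Non-epithelial cells of the same libraries, thinned alike, had 0.162%, 0.234%, 0.499% and 0.235%. Before thinning, the counted epithelial cells had median depths of 7110, 9849, 10003 and 14507 UMIs, and the non-epithelial ones 5473, 4869, 4619 and 5455 UMIs. In the Dicer1S2D lung library 0 of 61 such cells counted, which allows a share of up to 4.92%, beside 0.906% of its non-epithelial cells. The mean was 2.01% ± 0.722 in KrasLA1 and 21.3% ± 27.5 in the double mutant (SD, n = 2 each; exact permutation test, p = 0.667, smallest possible p = 0.333). Double-mutant library 2 decides the difference: 19.2 percentage points with it and -0.196 without it. In AT2-like clusters alone, the shares were 0.340%, 0.609%, 0 of 394 cells and 25.5%.

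**Figure D2:**
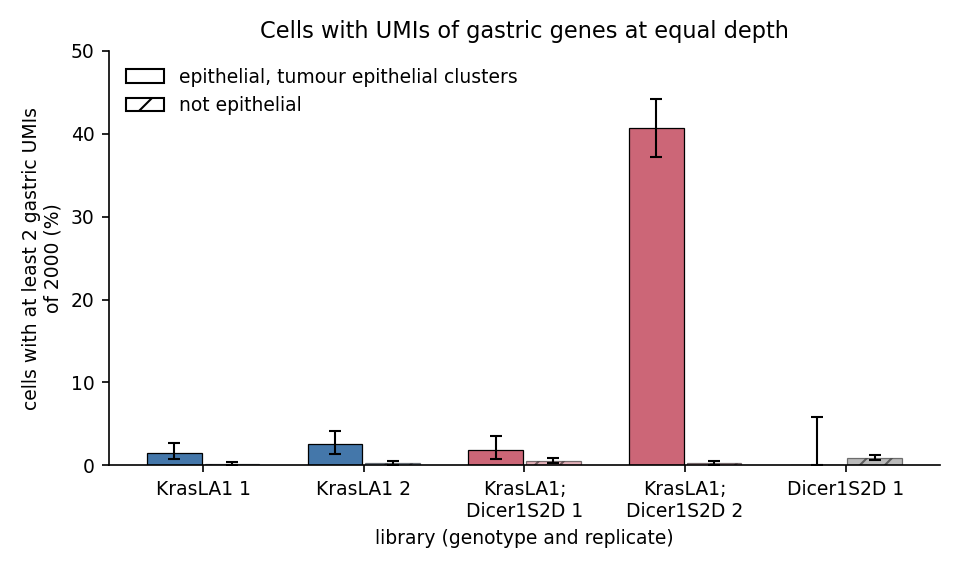
Share of cells (%) with at least 2 gastric UMIs among 2000, per library, in epithelial cells of the tumour epithelial clusters (plain bars) and in non-epithelial cells (hatched bars); error bars are exact 95% intervals. The bar at 40.7% is double-mutant library 2, where most of the gastric UMIs were of Gkn2. The epithelial shares of the other tumour libraries are between 1.5% and 2.53%.

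Intestinal and hepatic genes, as a list, rose in double-mutant tumour epithelial cells, with 6 of 6 measured members higher (camera, adjusted p = 4.39e-05). The list holds 24 genes, and the others did not pass the count filter. Phgr1, a gene of gut epithelium, had 3.58, 9.57, 13.9 and 141 CPM, the plasma albumin gene Alb 2.60, 2.49, 3.69 and 73.6 CPM, and the gut lectin gene Lgals4 1.95, 1.57, 1.05 and 9.52 CPM. Genes of the transitional, high-plasticity alveolar state rose as a list, with 18 of 20 higher (adjusted p = 4.39e-05). Among them S100a6, a calcium-binding protein gene, had 379, 822, 468 and 5175 CPM, and the integrin gene Itga2 3.09, 13.5, 11.8 and 112 CPM. Both calls ended with an estimated correlation (adjusted p = 0.704 with an estimated correlation for each). Of the class, 39.6% lay in the unnamed cluster in double-mutant library 2, and 6.42% to 10.4% in the others. The transitional list was not called without KrasLA1 library 1 (adjusted p = 0.0831) and was lower without double-mutant library 2 (adjusted p = 0.0157). The intestinal and hepatic list was called higher with any library left out, the only one of the 13 called lists of these cells to keep its call and direction so. The count filter was run anew in each of these fits, so the members tested can differ. In double-mutant library 1, Phgr1 and Alb lay above both KrasLA1 libraries and Lgals4 below both.

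KRAS and MAPK output genes rose as a list, with 10 of 16 higher (camera, adjusted p = 0.0307); the MAPK phosphatase gene Dusp6 had 114, 81.7, 115 and 352 CPM. Targets of the let-7 microRNA family, which DICER1 matures, rose as a list with 8 of 11 higher (adjusted p = 0.0329), among them Hmga2 with 0.488, 5.51, 5.45 and 17.9 CPM. Hypoxia and glycolysis genes, with 11 of 16 higher, and p53 targets, with 12 of 15 higher, rose as lists too (adjusted p = 0.0178 and 0.0149). The glycolytic gene Pkm had 94.4, 126, 113 and 272 CPM, and the stress cytokine gene Gdf15 44.6, 54.3, 31.3 and 389 CPM. All 4 calls ended with an estimated correlation (adjusted p = 0.704 with an estimated correlation, and 0.748 for hypoxia and glycolysis). Without double-mutant library 2 these 4 lists were lower and not called (adjusted p = 0.946, 0.752, 0.441 and 0.501, in that order). The KRAS list was also not called without KrasLA1 library 1 or 2 (adjusted p = 0.104 and 0.117), nor were the let-7 list (0.0831 and 0.0852) and the p53 list (0.0572 and 0.109).

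Alveolar identity genes fell as lists, in a class that the unnamed cluster fills to 39.6% in double-mutant library 2 and to between 6.42% and 10.4% in the others: 15 of 18 alveolar type 2 genes and 12 of 14 alveolar type 1 genes were lower in the double mutant (camera, adjusted p = 0.000751 and 0.0370). The surfactant protein gene Sftpd had 3756, 2827, 3095 and 1819 CPM, and Chil1 1296, 1889, 1129 and 1020 CPM; Fabp5, a lipid-binding member, was on the other side with 479, 457, 641 and 979 CPM. Antigen presentation genes fell as lists, with 8 of 8 MHC class II and 12 of 13 MHC class I genes lower (adjusted p = 0.00122 and 0.00112). The class II chain gene H2-Aa had 776, 986, 923 and 445 CPM, and B2m, the light chain of class I, 445, 443, 468 and 184 CPM. All 4 calls ended with an estimated correlation (adjusted p = 0.704 with an estimated correlation). Without double-mutant library 2 the type 2 and MHC class I lists were higher and not called (adjusted p = 0.0851 and 0.486), and the type 1 and MHC class II lists were not called (adjusted p = 0.893 and 0.576). Without KrasLA1 library 2 the type 1 list and both MHC lists were not called (adjusted p = 0.182, 0.172 for class II and 0.109 for class I), nor was the type 1 list without KrasLA1 library 1 (0.0738).

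Interferon-stimulated genes fell as a list, with 13 of 15 lower (camera, adjusted p = 4.39e-05); Ifi27l2a had 15.5, 12.5, 8.09 and 7.81 CPM. Genes of epithelial-mesenchymal transition fell, with 6 of 7 lower (adjusted p = 0.00485), among them the intermediate filament gene Vim with 51.1, 55.8, 35.7 and 22.9 CPM. Genes of the unfolded protein response fell, with 11 of 15 lower (adjusted p = 0.0252), among them the chaperone gene Sdf2l1 with 22.8, 35.0, 13.7 and 23.7 CPM. The 3 calls ended with an estimated correlation (adjusted p = 0.704 with an estimated correlation). Without KrasLA1 library 2 none of the 3 was called (adjusted p = 0.313, 0.169 and 0.109, in that order). The mesenchymal list was also not called without double-mutant library 2 (0.132), nor the unfolded protein list without KrasLA1 library 1 (0.100) or double-mutant library 1 (0.411).

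RNA of other cells was lower in double-mutant tumour epithelial cells, beside all of the lists above. Of the markers of other cells, 13 of 17 immune, 13 of 14 stromal, 5 of 6 ciliated or club and 5 of 5 erythroid genes were lower, as were 10 of 13 mitochondrially encoded genes. The immune, stromal, ciliated or club and mitochondrial lists were called lower (camera, adjusted p = 0.000537, 4.72e-05, 0.0101 and 0.0101) and the erythroid list was not (0.0640). With an estimated correlation 0 of these 5 was called (adjusted p = 0.228 to 0.482 with an estimated correlation). In all, 13 of the 23 lists were called, 6 higher and 7 lower, against 0 with an estimated correlation and 0 by fry. Within the 23 lists 0 members changed by edgeR, also 0 adjusted over the list alone. Lists not called, besides the gastric one, were gastrointestinal transcription factors (adjusted p = 0.617), lung lineage transcription factors (0.929), airway club and goblet genes (0.920), small RNA machinery (0.920), heterochromatin regulators (0.533), chromatin remodelling complexes (0.841), proliferation (0.532), cholesterol and fatty acid synthesis (0.876) and the immediate-early response (0.643). Of the 18 gastrointestinal transcription factors only 6 passed the count filter, so their list test covers those alone. Hnf4a, a member that did not pass it, had 1, 4, 3 and 441 UMIs, nearly all in double-mutant library 2. Mean and median log2 fold differed in sign for lung lineage transcription factors (0.000659 and -0.02) and small RNA machinery (-0.01 and 0.04).

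Proliferating cells made up 2.26% and 3.37% of KrasLA1 and 3.41% and 6.12% of double-mutant tumour epithelial cells at 2000 UMIs each (exact 95% intervals 1.27% to 3.69%, 2.07% to 5.15%, 1.92% to 5.56% and 4.55% to 8.04%). The difference of the means, 1.95 percentage points, gave an exact permutation p = 0.333 (n = 2 each), the smallest possible. It was 0.598 without double-mutant library 2, 3.31 without library 1, 0.440 at resolution 0.5 and 5.96 without thinning. With the strict cell filter it was 0.336, with the lenient one 3.57 and in AT2-like clusters alone 4.91. Thinned to 1000 UMIs, which admits more shallow cells, the difference was -0.314. Non-epithelial cells, which hold cycling macrophages, had 4.89%, 4.58%, 4.40% and 5.02%. The minimum of 2000 UMIs left out 648 of 1313, 433 of 1027, 401 of 841 and 370 of 1154 tumour epithelial cells. The AT2-like cluster led by the proliferation gene Ube2c had a median of only 1144 UMIs, so most of its cells were left out. It held 8.91%, 4.67%, 7.73% and 5.46% of the tumour epithelial cells, which did not separate the genotypes.

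Among the other cells of the tumours, 13 classes were tested and 3 genes changed, each in 1 class. Wls, which escorts WNT proteins to secretion, rose in NK cell-like cells, from 50.4 and 42.1 CPM in KrasLA1 to 350.4 and 355 CPM in the double mutant (log2 fold 2.91 ± 0.35 SE, edgeR adjusted p = 0.00586, n = 2 against 2). This class was small, with 98 and 83 cells in KrasLA1 and 63 and 21 in the double mutant. Its double-mutant libraries held 151245 and 56298 UMIs in all. With the strict cell filter NK cell-like cells were not among the classes tested. Ccl5, a chemokine that draws T cells, rose in interstitial macrophage-like cells, from 3 and 1 UMIs to 55 and 304 UMIs, or from 5.99 and 2.85 CPM to 112 and 125 CPM (log2 fold 4.66 ± 0.43, edgeR adjusted p = 0.0433). Chil3, a chitinase-like gene abundant in alveolar macrophages, fell in dendritic cell-like cells, from 243 and 252 CPM to 63.7 and 42.3 CPM (log2 fold -2.26 ± 0.26, edgeR adjusted p = 0.0350). Chil3 was not called with doublets left in (log2 fold -0.93, adjusted p = 0.999), at resolution 0.5 (-1.19) or with replicate number as a block (-2.28, adjusted p = 0.136). Ccl5 was not called with the lenient cell filter (2.17, adjusted p = 0.363) or the strict one (5.44, adjusted p = 0.199). The 3 genes were called with any library left out.

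Over the 13 classes, with 2300 to 11272 genes each, 2441 edgeR tests had an unadjusted p under 0.05. That is fewer than this threshold gives when no gene changes. In these totals a gene counts once for each class. DESeq2 called 38 and the replicate block 66. Without 1 library, edgeR called 117 to 846 genes, most without double-mutant library 1 and fewest without KrasLA1 library 1; without KrasLA1 library 2 the count was 275 and without double-mutant library 2 it was 204. Named values that did not pass include Cxcl9, an interferon-gamma-induced chemokine, in interstitial macrophage-like cells (11.97, 11.4, 266 and 128 CPM) and the cytokine gene Il1b in T cell-like cells (7.05, 19.3, 75.5 and 57.9 CPM). S100a9, a calcium-binding protein gene abundant in neutrophils, in T cell-like cells had 48.6, 130, 328 and 335 CPM. Both Il1b and S100a9 are among the leading genes of neutrophil-like clusters, and RNA of such cells in T cell-like cells was not estimated. The chemokine gene Ccl3 in neutrophil-like cells had 59.2, 100.2, 201 and 459 CPM, and the matrix protease gene Mmp3 in fibroblast-like cells 222, 334, 75.1 and 65.2 CPM. Thbs1, a matrix glycoprotein gene, had 2503, 1751, 483 and 310 CPM in mural cell-like cells. Sftpc, a surfactant gene of alveolar epithelium, had 4416, 3487, 1915 and 1405 CPM in T cell-like cells, and 2969, 1963, 1199 and 922 CPM in dendritic cell-like cells.

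**Figure D3:**
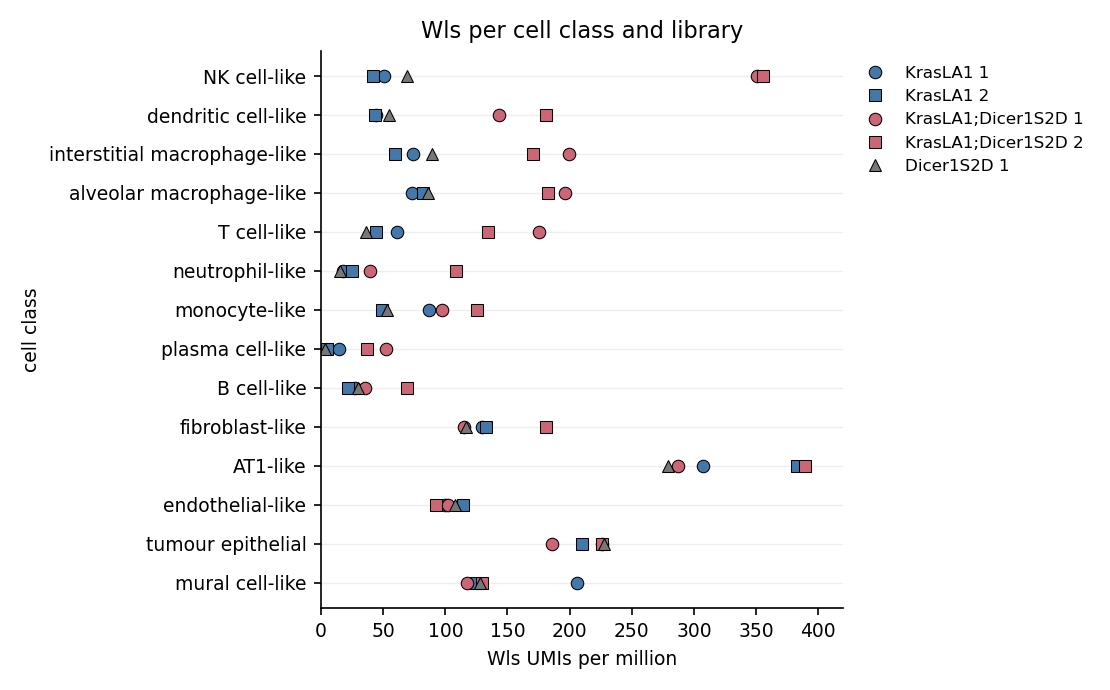
Wls in CPM (horizontal axis) per cell class (vertical axis), 1 point per library, with colour for genotype and symbol for replicate. In NK cell-like cells the double-mutant libraries are at 350.4 and 355 and the KrasLA1 libraries at 50.4 and 42.1, whereas in endothelial-like cells all 5 libraries are between 92.3 and 114.

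Gene lists were called 31 times in 164 tests over these classes, against 0 with an estimated correlation and 0 by fry, which tests a list's members against no change instead of against the other genes. Of the 31 calls, 5 were made in the same direction with any library left out, all of them named below, and 26 were not. Immediate-early genes, induced by stress and by tissue dissociation, fell as a list in fibroblast-like cells, with 18 of 18 lower (camera, adjusted p = 8.61e-14, and adjusted p = 0.595 with an estimated correlation). They also fell in mural cell-like cells, with 18 of 18 lower (1.92e-10, and adjusted p = 0.959 with an estimated correlation). Both of these calls were made with any library left out. In endothelial-like cells, of which 1 cluster held 50.4% in double-mutant library 2 and 8.61% to 15.8% in the others, 16 of 18 were lower (6.31e-06, and adjusted p = 0.636 with an estimated correlation), which was not called without KrasLA1 library 1 (0.309) or double-mutant library 2 (0.941).

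In neutrophil-like cells, MHC class II genes rose as a list, with 9 of 9 higher (camera, adjusted p = 6.41e-10), and so did inflammatory cytokines and chemokines, with 11 of 15 higher (6.02e-08). For each, adjusted p = 0.619 with an estimated correlation. In this class 4 of 13 lists were called as reported, against 1 of 12 with the lenient cell filter and 1 of 12 with doublets left in. These calls thus did not both hold under either alternative. With the strict cell filter neutrophil-like cells were not among the classes tested. Clusters filled the class unequally: the largest, led by G0s2 and Lst1, held 85.99%, 63.4%, 57.9% and 55.97% of it, and the one led by Retnlg and S100a8 4.50%, 11.6%, 14.2% and 21.6%. Of each of these lists 7 members changed adjusted over the list alone and 0 over all genes, and both were called with any library left out. In endothelial-like cells MHC class II genes fell instead, with 7 of 7 lower (7.56e-10, called with any library left out, and adjusted p = 0.636 with an estimated correlation); the difference between the classes was not tested. Interferon-stimulated genes rose in T cell-like cells, with 14 of 15 higher (camera, adjusted p = 0.00126, and adjusted p = 0.516 with an estimated correlation), but were not called there without KrasLA1 library 1 or double-mutant library 2. Clusters filled this class unequally too. The one led by Cd3g and Trdc held 41.9%, 46.3%, 46.6% and 59.6% of it, and the one led by Gm8369 and Trbc2 39.0%, 38.9%, 33.0% and 21.4%. Extracellular matrix genes rose in fibroblast-like cells, with 16 of 19 higher (0.00267, and adjusted p = 0.595 with an estimated correlation), and were lower and not called without double-mutant library 2 (0.0631). Besides these, the inflammatory list rose in interstitial macrophage-like cells with only 7 of 16 higher, a median log2 fold of -0.05, a mean of 0.46 and 1 member changed, Ccl5 (2 adjusted over the list alone; 0.00574, and adjusted p = 0.738 with an estimated correlation). Without KrasLA1 library 2 it was lower and not called (0.983), nor was it without double-mutant library 1 (0.585).

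Among cell classes, interstitial macrophage-like cells of double-mutant library 2 stood out by their share. These C1q- and Apoe-expressing macrophages made up 2.44% and 1.85% of kept cells in KrasLA1 and 2.55% and 13.5% in the double mutant (log2 fold 1.90 ± 0.68 SE, n = 2 against 2, edgeR adjusted p = 0.124). Plasmacytoid dendritic cell-like cells, which make type I interferon, numbered 2 and 6 in KrasLA1 and 15 and 10 in the double mutant (adjusted p = 0.188). Mesothelial-like cells numbered 10 and 16 against 2 and 3 (adjusted p = 0.194). AT2-like cells made up 15.7% and 19.4% against 16.4% and 16.7%, and T cell-like cells 8.52% and 10.8% against 10.4% and 8.07%. Of 20 classes edgeR called 0, with 4 at an unadjusted p under 0.05. It called the macrophages without double-mutant library 1 (log2 fold 2.65, adjusted p = 0.000706) and with doublets left in (1.84, adjusted p = 0.0494), and without double-mutant library 2 their log2 fold was 0.24 (adjusted p = 0.956). The other class called under these alternatives was the unnamed epithelial cluster, which is not read as a difference between genotypes because its leading genes differ between the libraries. Double-mutant library 2 lost the most barcodes to the mitochondrial limit, and shares are of the cells kept.

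**Figure D4:**
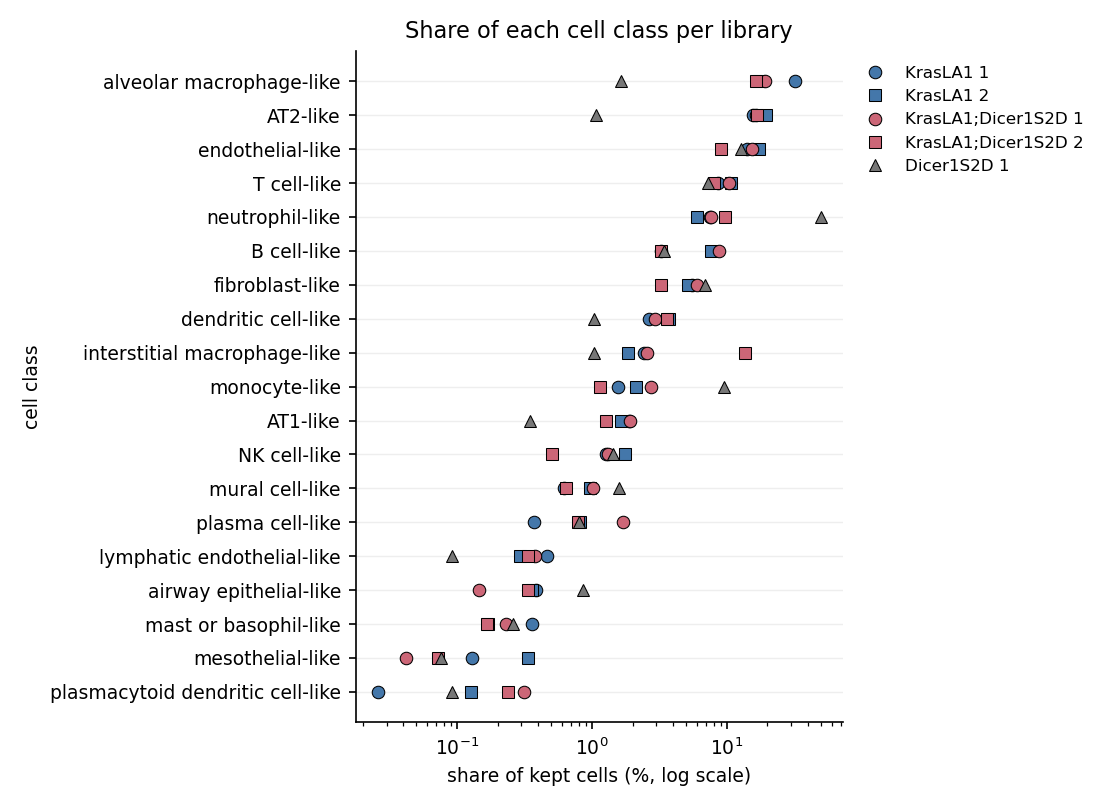
Share of kept cells (%, log scale) per cell class, 1 point per library, with colour for genotype and symbol for replicate. Interstitial macrophage-like cells are at 13.5% in double-mutant library 2 and between 1.85% and 2.55% in the other tumour libraries; neutrophil-like cells are at 49.8% in the Dicer1S2D lung library.

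The Dicer1S2D lung library, which asks what the Dicer1 allele goes with outside tumours, held other cells than the tumours and has no replicate. Neutrophil-like cells made up 49.8% of it (exact 95% interval 48.6% to 51.0%), monocyte-like cells 9.59% (8.89% to 10.3%) and AT2-like cells 1.08% (0.841% to 1.35%). In its 71 AT2-like cells, with 877189 UMIs, 32 genes lay at least 4-fold above all 4 tumour libraries and 8 at least 4-fold below. Car1, a carbonic anhydrase gene, had 196 CPM in the lung library and 0 UMIs in every tumour library, so it was at least 372-fold higher against a floor of 3 counts per library (lower 95% counting limit 299). The inflammatory genes Ccl2, Il6, Il1b, Cxcl2, Ptgs2 and Nfkbia were higher, as were 6 immediate-early genes. Ccl2 was 52.0-fold above the nearest tumour library (95% counting interval 33.4 to 82.9) at 92.3 CPM, and Il1b 25.7-fold (20.2 to 32.7) at 194 CPM. The neutrophil genes S100a8 and S100a9, markers of RNA from other cells, were 20.3-fold and 15.2-fold higher. If all of both were RNA of other lung cells, such RNA would bring up to 58.6% of the Il1b and 82.4% of the Cxcl2 found in these cells, so how much of these 2 AT2-like cells make is not known, and up to 6.07% of each of the other inflammatory and immediate-early genes. Airway epithelial cells were not among the sources, although the club cell gene Scgb1a1, at 2921 CPM, was among the 32 higher genes. RNA from airway cells was thus not estimated. On the lower side, the long non-coding RNA gene Meg3 had 1 UMI in the lung library, a ratio of 399 (interval 71.6 to 15769), and Dmkn had 2 UMIs, a ratio of 45.2 (12.5 to 374). Clu was 6.80-fold lower. The tumour side of these values includes the unnamed cluster, led by Gkn2, Clu and Meg3. Against the AT2-like clusters of the tumours alone, 29 of the 32 genes were still higher and 5 of the 8 still lower, with a ratio of 168 for Meg3 (interval 30.1 to 6640.4) and 38.6 for Dmkn; Clu, at 2.88, was no longer among them. On the higher side the ratio was at least 282 for Car1 against the same floor (lower 95% counting limit 227), 89.3 for Ccl2 and 22.1 for Il1b. None of the 18 alveolar type 2 genes met the rule in either direction. Gastric genes are mostly too low in the tumours for the rule to call them lower; Gkn2 had 0 UMIs in the lung library, which allows up to 3.42 CPM, against 5.51 CPM or more in the AT2-like clusters of the tumours and 30.3 CPM or more with the unnamed cluster. These values compare tissue, genotype and library at once.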

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

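In all, 268 results had 3511 values under 30 alternatives. Of the values of single genes, 2203 stayed on their side of the threshold, 300 passed it where the reported value did not, 5 no longer passed and 0 turned; for cell class shares, 201 stayed and 4 passed; for gene lists, 471 stayed, 7 passed, 191 no longer passed and 23 turned. To turn means here to change direction with a call before or after; a further 60 gene values, 24 class shares and 21 lists changed direction without a call in either and are counted as staying. The simulated data show that the spread between libraries limits the test to large changes; the effect of depth was not simulated. Replicate numbers gave no sign of pairing the libraries (correlation of the deviations of replicates 0.0413 over 11815 genes), so the replicate block is an alternative only. With 2 pairs, this check cannot exclude pairing. Unless said otherwise, the cause was not tested.

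Genes called in tumour epithelial cells, 0 as reported, were 301 without the filter on low counts, 2 with the replicate block, 3 with DESeq2 and 0 to 961 with 1 library left out. In the other classes, 3 as reported, they were 523 without the filter, 66 with the block, 38 with DESeq2, 10 with the lenient cell filter, 5 with doublets left in, 5 at Leiden resolution 0.5 and 117 to 846 with 1 library left out. The lists called were 0 with an estimated correlation and 0 by fry in both sets of classes, and 5 to 15 of 23 in tumour epithelial cells with 1 library left out. The class shares called were 2 with doublets left in and 0 to 2 with 1 library left out. The gastric share difference was between -0.196 and 38.7 percentage points with 1 library left out, and the proliferating share difference between 0.598 and 3.31, and -0.314 at a thinning to 1000 UMIs. The lung comparison held 162 genes at 2 times and 14 at 8 times, as a looser and a stricter size rule must move it.

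Lists that turned, as defined above, with 1 library left out had these lowest and highest adjusted p over the 4 libraries. In tumour epithelial cells: gastric 1.35e-08 and 0.620, alveolar type 2 2.76e-10 and 0.0851, transitional 2.74e-11 and 0.0831, airway 0.0155 and 0.766, KRAS and MAPK 0.0150 and 0.946, let-7 targets 0.0112 and 0.752, proliferation 0.0140 and 0.721, MHC class I 6.46e-07 and 0.486, cholesterol and fatty acid synthesis 9.52e-06 and 0.256, hypoxia and glycolysis 0.000127 and 0.441, p53 targets 0.000491 and 0.501. In alveolar macrophage-like cells: MHC class II 4.90e-16 and 0.728, hypoxia and glycolysis 2.97e-07 and 0.634, immediate-early 3.35e-05 and 0.922. In dendritic cell-like cells: cholesterol and fatty acid synthesis 4.92e-06 and 0.897. In endothelial-like cells: MHC class I 8.17e-05 and 0.941, hypoxia and glycolysis 0.0155 and 0.946. In fibroblast-like cells: MHC class II 1.56e-15 and 0.948, and 0.116 with the strict cell filter, unfolded protein response 7.38e-15 and 0.334, extracellular matrix 1.05e-15 and 0.0631. In interstitial macrophage-like cells: inflammatory cytokines and chemokines 0.00886 and 0.983.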

Other observations

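Of the tests below, 6 were chosen only after the result was seen: the 2 of free RNA and the 1 of the Dicer1S2D allele for Wls, and all 3 for the gastric genes of double-mutant library 2.

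In plasma cell-like cells, Ighg2b, a heavy chain of class-switched antibodies, had 182 and 33.4 CPM in KrasLA1 libraries 1 and 2 and 3699.6 and 8494 CPM in double-mutant libraries 1 and 2, without passing the edgeR test (edgeR adjusted p = 0.355, DESeq2 adjusted p = 0.000858). Ighm, the IgM heavy chain, had 81.5, 103, 1417 and 29459 CPM in the same order (adjusted p = 0.707 by edgeR and 0.00205 by DESeq2). In B cell-like cells, Ighg3 had 11.3, 0, 222 and 19.3 CPM, from only 5, 0, 212 and 7 UMIs, and Ighg2c 6.76, 0, 26.2 and 35.9 CPM; neither passed the test. Outside the lymphoid classes, Bex4 in AT1-like cells had 12.05, 15.7, 96.5 and 138 CPM (adjusted p = 0.232), and Chil3, the gene that fell in dendritic cell-like cells, had 386, 362, 878 and 1621 CPM in monocyte-like cells (adjusted p = 0.232).

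Wls also lay above both KrasLA1 libraries by at least 1.5 times in T cell-like cells (61.3, 44.4, 175 and 134 CPM), in alveolar macrophage-like cells (73.5, 81.8, 197 and 183 CPM) and in dendritic cell-like cells (43.8, 43.0, 144 and 181 CPM). In tumour epithelial cells it had 226, 210, 186 and 226 CPM. Gbp2b, a guanylate-binding protein gene induced by interferon gamma, had 0, 0, 13 and 15 UMIs in dendritic cell-like cells and 0.0737, 0, 7.53 and 8.35 CPM in alveolar macrophage-like cells.

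Wls, on chromosome 3 from 159839672 to 159938664, was apart between the genotypes in 7 of 14 classes. Gbp2b, on the same chromosome from 142594847 to 142619179, was apart in 6 of the 7 classes in which it had enough UMIs to be examined. Free RNA, its amount per class measured by Sftpc, is argued against for Wls in NK cell-like cells: in both double-mutant libraries it would bring to another class at least 2.90 times the upper limit of all Wls found there (1.58 within counting error). The same test argues against it in 3 of the 6 other classes (alveolar macrophage-like, dendritic cell-like and interstitial macrophage-like) and does not decide in T cell-like, neutrophil-like and plasma cell-like cells. Sftpc had 4416, 3487, 1915 and 1405 CPM in T cell-like cells and 6750, 4463, 2898 and 1632 CPM in neutrophil-like cells. Wls in tumour epithelial cells was no higher in the double mutant. This argues against RNA freed from alveolar epithelial cells in T cell-like and neutrophil-like cells. Free RNA stays open in plasma cell-like cells (Sftpc 1313, 778, 2144 and 339 CPM), as does free RNA from other sources. A strain haplotype on chromosome 3 may underlie both genes and stays open: of the 20 other genes apart in at least 4 classes (22 in all, against 17 and 49 for the other 2 splits of the 4 libraries), 2 lie there, a ratio of 2.08 to the genes examined (Fisher exact p = 0.250, with genes that are not independent), but these are Chia1 and Muc1, alveolar epithelial genes that were lower as Sftpc was, so the ratio does not speak for it. The Dicer1S2D allele stays open too: Wls lay above the midpoint of the genotypes in 0 of 7 classes of the Dicer1S2D lung library, and Gbp2b in 0 of 6, but that library is single and from another tissue.

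Gastric genes, by UMIs mostly Gkn2, stood apart in double-mutant library 2. Deeper cells there are argued against, since at equal depth its gastric share was 16.1 times the highest of the other tumour libraries. Free RNA from other cells is argued against by a share 173 times that of the library's own non-epithelial cells. The double-mutant genotype may still contribute, but only 1 of the 2 double-mutant libraries shows the pattern: library 1 lay -0.707 percentage points from the higher KrasLA1 library. A difference between tumours or animals that the labels do not record was not tested.

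Surfactant transcripts in non-epithelial classes were lower in both double-mutant libraries than in both KrasLA1 libraries in 9 of 12 classes, with a median Sftpc of 4829 and 3024 CPM in KrasLA1 libraries 1 and 2 and 2282 and 1127 CPM in the double mutant. Free RNA from alveolar epithelial cells, which carries the same mixture into each class, may account for it: within a library, the share of Sftpc among 5 alveolar type 2 transcripts had an SD of only 1.52 percentage points between classes (median of the libraries), while it ranged from 66.4% to 81.3% over all classes and libraries. The test does not say why less of it is found in the double mutant, and no biological explanation was tested. In tumour epithelial cells themselves, Sftpc had 120238 and 119928 CPM in KrasLA1 libraries 1 and 2 and 120988 and 54362 CPM in double-mutant libraries 1 and 2. It was thus lower there in double-mutant library 2 but not in library 1.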
